A study of Mus musculus with 4 samples.

How the data were processed

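RNA of 2 mouse testicular germ cell lines, GC-1 and GC-2, was measured on 4 one-colour Agilent whole-genome expression arrays, 2 per line. Per the labels, cells were grown in serum-supplemented medium, harvested near confluence into Trizol, and their total RNA was amplified with an oligo-dT primer and labelled with Cy3. Lines and replicate numbers were taken from the sample titles. The titles do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

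Per the file headers, the arrays were quantified with Agilent Feature Extraction 11.5.1.1, which gives each spot a processed intensity: the Cy3 brightness after background subtraction and spatial detrending, with a surrogate value for spots not above background, and with no normalization between arrays. The deposited scanner files also hold the raw mean intensity of each spot, the median intensity of its local background, and flags of 0 or 1 for spots well above background, positive and significant, saturated or irregular. The authors' series table holds log2 values with 1 value per gene name. For 381 rows named by a probe, the deposited log2 values equalled that probe's log2 processed intensity minus 1 constant per array. The SD of the difference was 0.00174 to 0.00237. Rows named by a gene were not set against the scanner values in this way. The column medians of the whole series table were -3.78 and -3.67 for GC-1 and -3.64 and -3.53 for GC-2. Genes were not centred, and how several probes of a gene were combined is not given in the sources used here.

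The values analysed were log2 processed intensities, averaged over the spots of a probe without control spots and spots marked as irregular (92 to 224 per array), minus the array's 75th percentile over 56605 probes. No spot was saturated. A probe was tested if it was well above background on both arrays of at least 1 line and had a value on all 4 arrays. These criteria left 36692 probes, and 34 others lacked a value. Lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, GC-2 minus GC-1, two-sided), with Benjamini-Hochberg adjustment over the probes and a threshold of 0.05. A gene was represented by its tested probe with the highest mean. Probe names came from the RefSeq gene table of GRCm38, used for names alone: 32994 probes were named by accession, 10224 by symbol and 520 by synonym, and 12867 kept the name in the scanner files. Probes of 24813 reference genes resulted. Probe positions are those of the scanner files, on mm9.

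A probe well above background on no array of a line has only a bound there. For such probes the brighter line's mean was set against the mean, over the arrays of the dimmer line, of the lowest signal among probes well above background or the probe's own signal if higher, and the result is given as at least N-fold. A gene counted as measured in a line if at least 1 of its probes was well above background on both arrays. The 28 gene lists held 745 entries, 742 with a probe. Gcna, Insl3 and Bcl2a1a had none and Ctgf was measured as Ccn2. Lists with at least 5 tested members were tested with camera of limma (preset correlation 0.01, adjusted over 27 lists). For each list, the genes past the threshold were counted over all genes tested and adjusted over the list alone. Measured members were compared with the other genes by two-sided Fisher's exact test, adjusted over lists and lines.

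Genes to be named were chosen by rule. They were the 6 largest rises and falls among genes with a probe well above background on all 4 arrays, the 6 largest bounds per direction among genes measured in 1 line and above background on no array of the other, up to 4 members past the threshold per list with the largest changes, the germ cell list members measured in both lines, and a fixed set of marker genes. For the germ cell members measured in both lines, only a selection is printed, chosen after the values were seen. Clone, Riken, predicted and accession names were left out of the 2 first groups. The samples, tests, lists, naming rule and alternatives were set before the data were examined, except where said otherwise.

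The limma step was tested on simulated data of 36692 probes with the measured means. Each probe's spread was drawn from limma's fitted prior, with independent normal noise, as limma assumes. Correlated errors and extra noise of dim probes were not simulated. With the called probes changed as measured, 55% of 2-fold and 98% of 4-fold changes were called, 99.96% of calls had the right sign and 2.62% fell on unchanged probes. With only 200 probes changed, no probe was called. The list test was simulated over 17437 genes with independent noise, all members of 2 lists shifted by the same amount and no other gene changed. It called 2 of 2 shifted lists and 0 of the others. Members that correlate or change by unlike amounts, as in these data, were not simulated. Alternatives tried were normexp background correction (offset 50), quantile, median and cyclic loess normalization, other filters on dim probes, a variance trend, the replicate number as a block, the mean of a gene's probes, the authors' log2 table, limma's treat against a fold of 1.5, fry, camera with an estimated correlation, other meanings of measured, and leaving out each array. Extraction and plots used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.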

Results

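The mouse lines GC-1 and GC-2 were made by transforming male germ cells. GC-1 was derived from type B spermatogonia with SV40 large T antigen, and GC-2 from spermatocytes with large T antigen and a temperature-sensitive p53. The series revisits the characteristics of these lines, and its design gives 1 comparison, GC-2 (n = 2 arrays) against GC-1 (n = 2 arrays). The 75th percentile of the processed signal was 666 and 693 on the GC-1 arrays and 416 and 199.9 on the GC-2 arrays, and 64.9%, 63.6%, 62.0% and 57.5% of the probes were well above background. The number of arrays limits the precision. Over 30316 probes well above background on all 4 arrays, Pearson's r across probes was 0.989 within GC-1, 0.990 within GC-2 and 0.896 to 0.910 between the lines, with genes not being independent replicates. The median SD between replicates was 0.20 log2 in GC-1 and 0.17 log2 in GC-2. All 4 arrays lay on 1 slide, with the arrays of each line in a row of their own, so that position on the slide and line cannot be told apart.

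Among genes well above background on all 4 arrays, the largest falls in GC-2 included keratins and a uroplakin, and the largest rises a chemokine and a meiosis gene. Krt18, an epithelial keratin, fell by 11.51 ± 0.24 log2 (SE, n = 2 arrays per line) in GC-2, with its probe at chromosome 15, 101862341 to 101862400 (mm9). Trf, which encodes transferrin, fell by 11.22 ± 0.23, the uroplakin Upk1b fell by 11.13 ± 0.32, and the keratin Krt14 fell by 10.20 ± 0.24. The envoplakin gene Evpl and the retinol carrier Rbp4 fell by 9.22 ± 0.35 and 9.11 ± 0.27. In the other direction the chemokine Cxcl12 rose by 10.81 ± 0.23, with its probe at chromosome 6, 117131227 to 117131286 (mm9), and the Wnt modulator Sfrp2 rose by 10.13 ± 0.67. The peptide hormone gene Cck rose by 9.54 ± 0.71, the synaptonemal complex gene Syce2 by 9.47 ± 0.26, Plac8 by 9.03 ± 0.27 and the heat shock gene Hspa1b by 8.73 ± 0.48. limma's adjusted p lay between 9.06e-05 for Krt18 and 0.000583 for Cck.

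**Figure D1:**
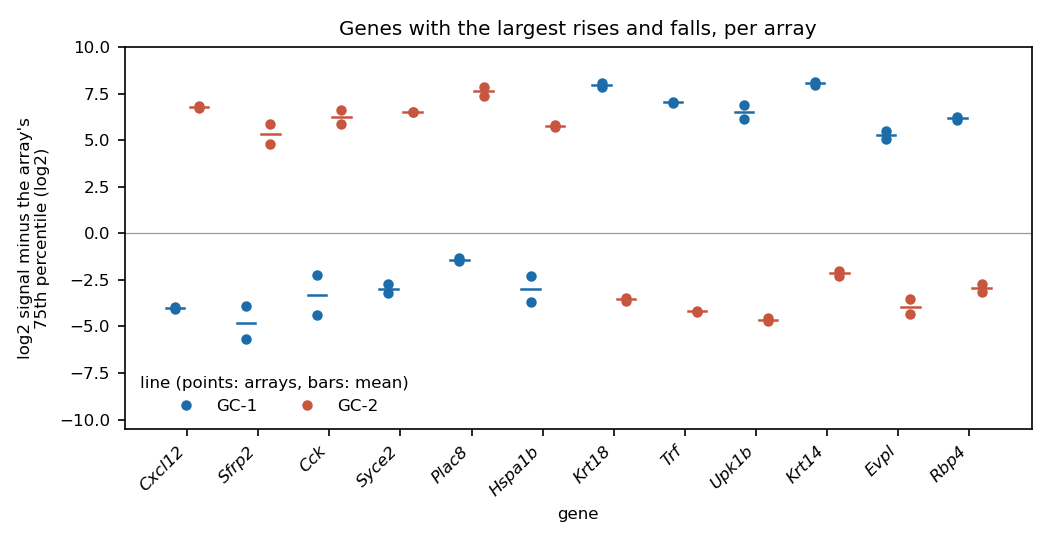
Log2 processed signal minus the array's 75th percentile (y axis, log2) for the 6 genes with the largest rises and the 6 with the largest falls among genes measured on all 4 arrays (x axis). Points are arrays, bars are means of the 2 arrays of a line, and for each gene both arrays of one line lie above 4 and both arrays of the other lie below -1.

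Other genes were well above background in 1 line alone. In GC-2 the BMP antagonist Grem1 was at least 1894-fold higher, the lectin-like receptor gene Klra4 at least 1126-fold, Gpnmb at least 648-fold, Olfm1 at least 425-fold, Syt13 at least 411-fold and B3galnt1 at least 394-fold. In GC-1 the interferon-inducible gene Ifi202b was at least 2390.0-fold higher, the growth factor gene Fgf5 at least 1028-fold, the uroplakin Upk3b at least 960.0-fold, Prr15l at least 649-fold, the chemokine receptor gene Ccr7 at least 567-fold and the kinase gene Ripk4 at least 541-fold. In all, 1045 genes were above background on both GC-1 arrays and on no GC-2 array, 722 of them past limma's threshold. The reverse held for 304 genes, all past that threshold. The limit of detection differed between the lines. On the normalized scale the lowest log2 value well above background was -6.19 and -5.92 on the GC-1 arrays. It was -5.58 and -4.69 on the GC-2 arrays. A dim gene of equal level in both lines could thus be missed in GC-2 alone. How far this accounts for the unequal counts was not tested.

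Of 17437 genes tested with limma, 3192 were higher and 4490 lower in GC-2 at an adjusted p under 0.05, and 6426 of these 7682 differed at least 2-fold. Of 36692 probes, 8845 were higher and 7935 lower. Without GC-1 replicate 1, 4634 genes passed, with 1986 higher and 2648 lower. Without GC-2 replicate 2, 2049 were higher. Of 7805 genes with several tested probes, 658 had probes past the threshold in opposite directions. The median log2 change of all genes was -0.13, and it moved between -0.20 and 0.20 with the normalization, background and filter, so that single changes of this size have no settled direction. All rises and falls are relative to the 75th percentile. In a comparison made after the data were seen, the E1A spike-in probes were 2.06 log2 higher on the GC-2 arrays on this scale (SD 0.46 over 8 probes, higher for all 8). Scaled to them, every change would be lower by about that much, rises below it would become falls, and the counts of higher and lower genes would change.

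Meiotic, spermatid and germ line genes were measured less often than other genes in GC-2, while the spermatogonial lists did not pass the test, and several of the best known were absent from the measured set. Dazl and Kit, a germ cell RNA-binding protein and the receptor of differentiating spermatogonia, were well above background on no array. Stra8, needed for entry into meiosis, and the synaptonemal complex gene Sycp1 were above it on 1 GC-1 array, and Sycp3 on 1 GC-2 array. The germ line helicase gene Ddx4 was above it on both GC-1 arrays and 1 GC-2 array, at signals of 12.9 and 12.7 in GC-1. Of 154 genes over the 5 germ cell lists, 92 were measured in GC-1, 68 in GC-2 and 67 in both, while 68.5% and 62.5% of all named genes were. In GC-2, 16 of 43 meiotic prophase genes, 17 of 42 spermatid genes and 11 of 29 germ line and piRNA genes were measured (Fisher's exact test, adjusted p = 0.00273, 0.01005 and 0.0239). In GC-1 the counts were 24, 23 and 14 (same test, adjusted p = 0.154, 0.117 and 0.0528). These GC-1 shares, 55.8%, 54.8% and 48.3%, also lay below that of all named genes, and the lines were not tested against each other. On the normalized scale the GC-2 arrays had the higher limit of detection. For undifferentiated spermatogonia 20 of 25 genes were measured in GC-1 and 17 in GC-2, and for differentiating spermatogonia 11 and 7 of 15 (adjusted p = 0.371 and 0.734, then 0.833 and 0.371). Of 96 probes for non-mouse ERCC control RNAs, whose addition is not stated, 8 passed the flag used on both GC-1 arrays and 3 on both GC-2 arrays, and of 308 negative control spots per array 0, 1, 0 and 0 passed it. Above the brightest such probe of each array, a limit chosen after the data were seen, 44 of the 154 germ cell genes remained in each line, against 52.9% of all named genes in GC-1 and 50.7% in GC-2, so that the share was below that of all genes in both lines, which was not tested. In both lines 36 remained, among them Etv5, Bcl6b, Sall4, Foxo1, Uchl1, Dmrt1, Rarg, Taf7l, Tdrd7, Ybx2, Brdt, Rec8, Prdm9, Psmc3ip, Mnd1, Trip13, Mybl1, Odf2 and Crem. The lists were not limited to genes confined to germ cells, and Ccnd2, Itga6 and Mcam also remained, while Mael, Piwil1 and Dmc1 were measured in neither line. The genes that remained therefore do not by themselves tell of germ cell identity.

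**Figure D2:**
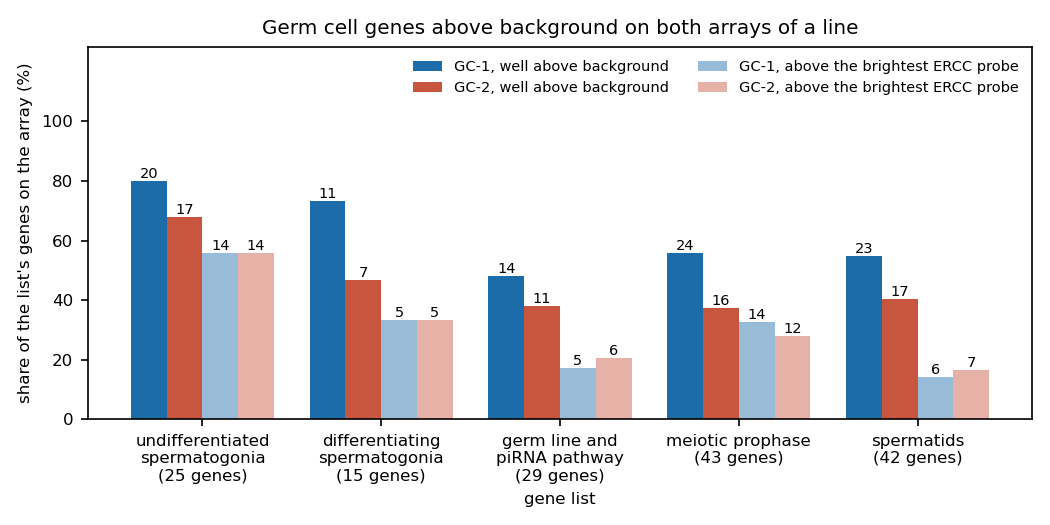
Share of each list's genes on the array (y axis, %) measured in each line for the 5 germ cell lists (x axis), with the number of genes over each bar. Full bars count genes well above background on both arrays, pale bars those above the brightest ERCC probe, and the undifferentiated spermatogonia list has the highest share, 20 of 25 genes in GC-1 and 17 in GC-2.

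Among tested germ cell genes the changes went both ways. Of 24 meiotic prophase genes 3 rose and 7 fell, the same as adjusted over the list alone. Beside Syce2, the DNA-binding meiosis gene Meiob and the histone reader gene Zcwpw1 rose by 4.60 ± 0.33 and 3.72 ± 0.43. The cohesin gene Stag3 was at least 6.12-fold and the double-strand break gene Mei4 at least 5.92-fold higher in GC-1, and Rec114, measured on 1 GC-2 array, fell by 5.37 ± 0.74. Of 20 undifferentiated spermatogonial genes 4 rose and 6 fell (4 and 7 adjusted over the list alone). The GDNF receptor gene Gfra1 rose by 4.52 ± 0.35, Bcl6b fell by 5.24 ± 0.25, Tspan8 was at least 213-fold higher in GC-1, and Uchl1 fell by 2.20 ± 0.41, although the mean of its probes fell by 0.34. Of 11 differentiating spermatogonial genes 2 rose and 1 fell, of 15 germ line and piRNA genes 2 rose and 4 fell, and of 23 spermatid genes 4 rose and 5 fell, with the same counts adjusted over the list alone. The retinoid binding gene Crabp1 rose by 3.34 ± 0.25, Rnf17 by 4.09 ± 0.35, and Tex15 was at least 8.85-fold higher in GC-2. The sperm ion channel genes Catsper2 and Catsper4 fell by 3.54 ± 0.23 and 2.22 ± 0.24, while the protamine gene Prm1 stood at -0.38 ± 0.40 and the acrosin gene Acr was above background on 1 of 2 GC-2 arrays. None of these 5 lists shifted against the other genes (camera, adjusted p from 0.620 to 0.902). Tested alone with fry, the spermatid and differentiating spermatogonia lists passed (adjusted p = 0.0153 and 0.0470) and the others did not. Of 15 pluripotency genes 2 rose and 7 fell, as adjusted over the list alone (camera, adjusted p = 0.599), with Klf2 down by a log2 change of -4.60 ± 0.24 and Tdgf1 by one of -3.21 ± 0.23.

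Markers of Sertoli cells, the nurse cells of the tubule, were lower in GC-2 as a group. Of 21 tested, 14 fell and 4 rose, also adjusted over the list alone (camera, adjusted p = 0.0339, and 0.925 with an estimated correlation). With an estimated correlation camera gave every list an adjusted p of at least 0.925, whatever the estimate. Beside Krt18 and Trf, Wt1, a transcription factor of Sertoli cells and of mesothelium, fell by 6.29 ± 0.26. Krt18 and Wt1 are not specific to Sertoli cells, and a list of other mesothelial genes, written after the data were seen, fell as well (16 of 22, median -4.35). Sox9, which directs Sertoli fate, was higher in GC-2 on the normalized scale, against the direction of the list, but short of limma's threshold. Its signals before normalization were 85.1 and 87.7 on the GC-1 arrays and 61.9 and 100.4 on the GC-2 arrays. The transcription factor gene Gata4 rose by 2.20 ± 0.26. Without GC-1 replicate 1 the list's adjusted p was 0.0707, and it lay between 0.0525 and 0.0698 under normexp, median centring, a filter on all 4 arrays or the authors' log2 table.

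Of 13 genes of Leydig cells and steroid synthesis 7 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.146). The steroidogenic factor gene Nr5a1 rose by 6.18 ± 0.23, the steroid hydroxylase gene Cyp17a1 by 3.40 ± 0.29 and Star, which moves cholesterol into mitochondria, by 2.75 ± 0.50, although Star had an adjusted p of 0.0582 without GC-1 replicate 1. The hydroxysteroid dehydrogenase gene Akr1c14 fell by 3.88 ± 0.47. Of 14 peritubular myoid genes 5 rose and 2 fell (6 and 3 adjusted over the list alone; camera, adjusted p = 0.275), with Myl9 up 5.93 ± 0.48 and Actg2 up 2.41 ± 0.28. Acta2 was up 1.80 ± 0.26 on its brightest probe, against 0.82 over the mean of its probes. Of 11 macrophage genes 4 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.620). The class II genes H2-Ab1 and H2-Eb1, each above background on 1 GC-1 array, rose by 7.38 ± 0.64 and 4.39 ± 0.48, and Cd68 fell by 4.78 ± 0.37. Of 9 endothelial genes 4 rose and 1 fell (5 and 1 adjusted over the list alone; camera, adjusted p = 0.318), with Eng up 5.88 ± 0.35 and Flt1 at -8.39 ± 0.26.

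Epithelial genes fell in GC-2 as a group. Of 19 tested, 12 fell and 2 rose, also adjusted over the list alone (camera, adjusted p = 0.0132; adjusted p = 0.925 with an estimated correlation). The keratin Krt19 fell by 7.68 ± 0.30. Krt8 and the desmosomal gene Dsp were at least 49.5-fold and 39.7-fold higher in GC-1. Cdh1, the E-cadherin gene, was above background on 1 GC-2 array alone, and Krt18 belongs to this list and to that of Sertoli cells. The list's median change was -3.60 as measured and -1.29 with the 7 members above background on no GC-2 array set at their bounds. The mean change of -3.07 became -1.57 under normexp (camera, adjusted p = 0.121), while with a filter on all 4 arrays, which left 9 members, it was -3.44 (adjusted p = 0.0572). Of 22 junction genes 11 fell and 3 rose, also adjusted over the list alone (camera, adjusted p = 0.146), with the cingulin gene Cgn at -4.28 ± 0.35 and Jam2 at -2.47 ± 0.30.

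Of 36 extracellular matrix genes 11 rose and 7 fell, also adjusted over the list alone (camera, adjusted p = 0.345). Col6a3, the proteoglycan gene Bgn and the receptor gene Pdgfrb rose by 6.31 ± 0.26, 6.13 ± 0.30 and 5.56 ± 0.38, while Dcn fell by 6.05 ± 0.37 and Col1a1 by 1.75 ± 0.31. Of 15 mesenchymal regulators 3 rose and 1 fell, also adjusted over the list alone (camera, adjusted p = 0.444). Fosl1 rose by 2.73 ± 0.31. Vim stood at -0.31 ± 0.26 and Cdh2 at -0.20 ± 0.34, both short of the threshold and well above background on all 4 arrays.

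Interferon response genes were higher in GC-2 relative to other genes, although their median rise of 0.84 log2 would be a fall if scaled to the spike-in probes. Of 35 tested, 14 rose and 0 fell, also adjusted over the list alone (camera, adjusted p = 0.000123; adjusted p = 0.925 with an estimated correlation). All 35 were measured in both lines. The restriction factor gene Trim30a rose by 3.17 ± 0.51, the guanylate-binding protein gene Gbp2 by 2.38 ± 0.53 and the class I gene H2-D1 by 2.38 ± 0.27. Psmb9, an immunoproteasome gene, rose by 2.16 ± 0.30 but stood at -1.76 in the authors' log2 table. Gbp2 had an adjusted p of 0.0643 without GC-2 replicate 2. The mean change was 0.99 log2, 0.61 without GC-1 replicate 1 and 1.36 without GC-1 replicate 2, and fry, which tests the list alone, gave an adjusted p of 0.136.

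Trp53, which encodes p53, rose by 4.39 ± 0.66 in GC-2 (limma, adjusted p = 0.00463). GC-2 was made with a temperature-sensitive p53, and whether the probe read that gene or the cell's own cannot be told from these values. Its signals were 495 and 2113 on the GC-1 arrays and 14409 and 5791 on the GC-2 arrays. Of 32 p53 targets 4 rose and 6 fell (3 and 6 adjusted over the list alone; camera, adjusted p = 0.902). Cdkn1a stood at 0.44 ± 0.40 and Mdm2 at 0.74 ± 0.38, short of the threshold, although both passed it, at 1.27 and 1.07, over the mean of their probes. Perp and Pmaip1, an apoptosis gene, fell by 5.28 ± 0.41 and 2.81 ± 0.43, and the receptor gene Eda2r was at least 11.1-fold higher in GC-2. Of 26 BCL2 family and caspase genes 5 rose and 10 fell, also adjusted over the list alone (camera, adjusted p = 0.620), with Bcl2 at -2.85 ± 0.31, Bok at -2.72 ± 0.24 and Birc3 up 2.52 ± 0.30. Of 30 G1/S genes 4 rose and 2 fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.620), and of 29 G2/M genes 1 rose and 3 fell (0 and 1 adjusted over the list alone; camera, adjusted p = 0.902). Mcm2 rose by 1.51 ± 0.25, and this rise and the medians of both lists (0.09 and -0.15 log2) would be falls if scaled to the spike-in probes, while Aurka fell by 1.56 ± 0.26 and the proliferation marker Mki67 stood at 0.57 ± 0.28.

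Metabolic lists changed in both directions, and the counts adjusted over the list alone were the same. Of 23 cholesterol synthesis genes 5 rose and 6 fell, of 21 glycolysis genes 3 rose and 3 fell, and of 21 antioxidant genes 6 rose and 7 fell (camera, adjusted p = 0.902, 0.620 and 0.902). Eno2 fell by 2.46 ± 0.27 and Pfkl rose by 1.68 ± 0.23. The catalase gene Cat fell by 2.69 ± 0.28, Gsta4 by 3.22 ± 0.51, and the glutathione synthesis gene Gclc rose (limma, adjusted p = 0.00126). Of the common reference genes, Actb rose by 0.97 ± 0.28 (limma, adjusted p = 0.0363) and Gapdh stood at 0.70 ± 0.26 (adjusted p = 0.0756), both of them falls if scaled to the spike-in probes. Under quantile normalization they stood at 0.28 and 0.05, Gapdh passed the threshold at 1.60 over the mean of its probes, and without GC-1 replicate 1, GC-1 replicate 2 or GC-2 replicate 2 Actb had adjusted p of 0.124, 0.122 and 0.148.

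Of 24 hormone and retinoid receptor genes 6 rose and 8 fell, and of 31 TGF-beta and BMP genes 8 rose and 11 fell, also adjusted over the list alone (camera, adjusted p = 0.902 and 0.872). Pparg rose by 2.86 ± 0.38, the mineralocorticoid receptor gene Nr3c2 was at least 22.6-fold higher in GC-1, and Bmp7 was at least 53.7-fold higher in GC-1 while Bmp2 was at least 6.04-fold higher in GC-2. Of 35 Hox genes 13 rose and 8 fell (14 and 9 adjusted over the list alone; camera, adjusted p = 0.213). Hoxd10 and Hoxd9 rose by 5.27 ± 0.24 and 4.45 ± 0.24, and Hoxd13 and Hoxd11 were at least 19.6-fold and 15.5-fold higher in GC-2. Of 23 imprinted genes 7 rose and 9 fell, also adjusted over the list alone (camera, adjusted p = 0.902). Peg3 was at least 285-fold and Grb10 at least 17.4-fold higher in GC-1, Ndn was at least 96.1-fold higher in GC-2, another probe took the place of that of Grb10 without GC-1 replicate 1 or 2 (at -3.73 and -3.24), and Sgce, above background on 1 GC-1 array, rose by 8.23 ± 0.58. Of 10 sex-chromosome genes 2 were measured in each line (Fisher's exact test, adjusted p = 0.00608 and 0.0176), too few for a list test. Kdm5d rose by 2.43 ± 0.24 on 1 of its 6 probes, the other 5 being above background on no array, and Uba1y stood at -0.80 ± 0.23, both past the threshold and so adjusted over the list alone, although Uba1y missed it without any 1 of the arrays. Median, mean and camera direction differed in sign for the undifferentiated and differentiating spermatogonia, germ line, spermatid, p53, cholesterol, antioxidant and hormone receptor lists.

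**Figure D3:**
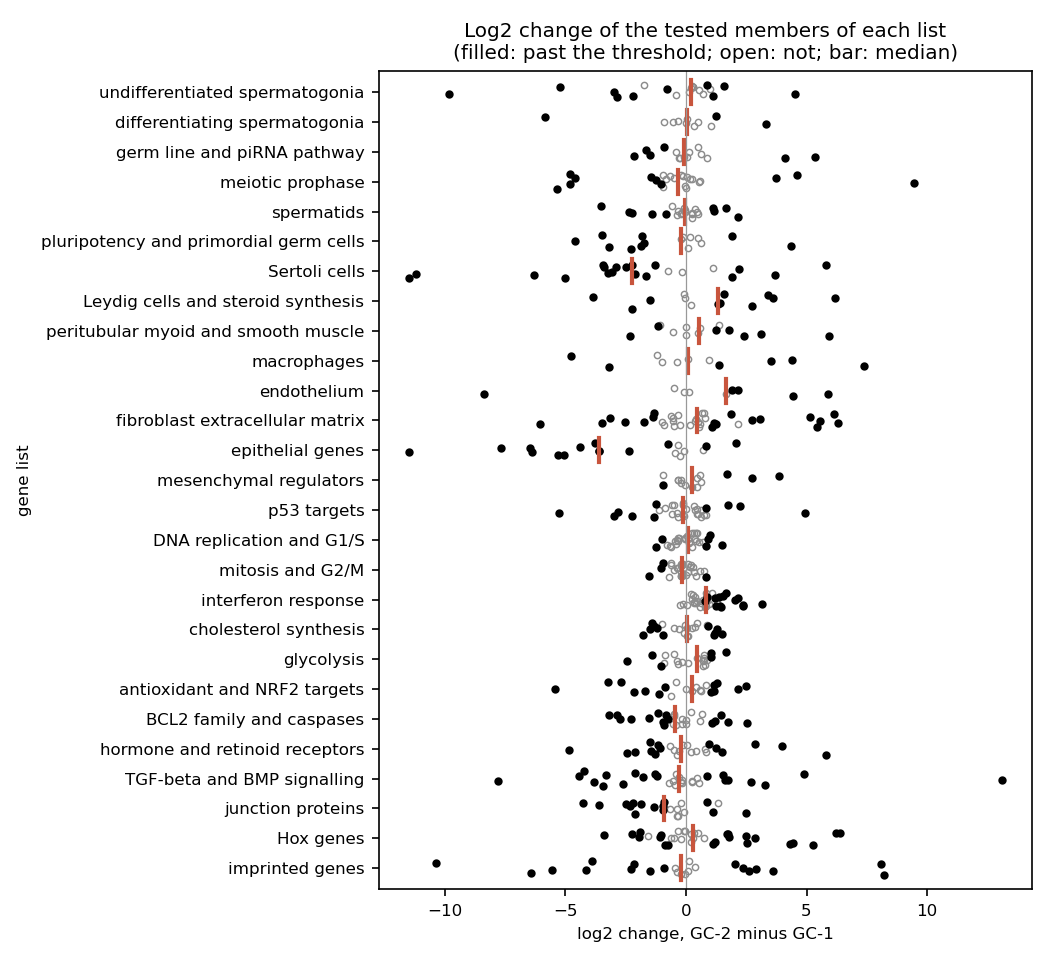
Log2 change, GC-2 minus GC-1 (x axis), of each tested member of the 27 lists (y axis). Filled points passed limma's threshold, open points did not, and bars are list medians, which lie furthest left for epithelial genes (-3.60) and Sertoli cells (-2.25).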

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

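The count of ERCC probes was made after the data were seen. The array carries probes for ERCC control RNAs, which no mouse gene encodes and whose addition is not stated. Of 96 such probes, 8 were well above background on both GC-1 arrays and 3 on both GC-2 arrays, while of 308 negative control spots per array 1 spot on 1 GC-1 array was. The brightest ERCC probe gave signals of 75.5 and 64.9 on the GC-1 arrays and 51.2 and 32.5 on the GC-2 arrays.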

How the results depend on the processing

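Cyclic loess and the limit from ERCC probes were chosen after the data were seen. The genes differing between GC-2 and GC-1 numbered 4634 to 5981 when 1 array was left out, with 1986 to 2503 higher and 2648 to 3478 lower, over 10683 to 13569 probes. The lone array of a line was then assumed to vary like the other line. Against a fold of 1.5, limma's treat called 4380 genes, 1786 higher and 2594 lower, and 10037 probes. Under other settings these counts stayed within 1.5 times. The split of genes moved, however, with 4166 higher and 4077 lower over the mean of a gene's probes. It was 3273 and 3475 under normexp, 3093 and 3412 in the authors' log2 table, and 2959 and 4835 under median centring. The higher share of probe calls was 52.7%, and 65.3% under normexp. With the replicate number as a block, limma called 7797 genes differing between GC-2 and GC-1, 3255 higher and 4542 lower, and the same 3 lists. The differences between replicates 1 and 2 of the lines correlated at 0.146 across probes, and with 2 pairs the samples share only a number. No slide block was run because all arrays lay on 1 slide.

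With an estimated correlation camera called 0 lists, fry 11, and leaving out 1 array 2 to 3. Above the brightest ERCC probe 44 germ cell genes were counted in GC-1 and 44 in GC-2, against 92 to 97 and 70 to 80 from single replicates. The median SD of GC-2 over all probes was 0.31. The causes of these moves were not tested, apart from fewer samples or a stricter threshold by construction. Camera's unadjusted p rose with an estimated correlation also where the estimate was near or under the preset 0.01. It went from 0.0270 to 0.163 for junction genes (estimate 0.0128) and from 0.0233 to 0.138 for Leydig cells (estimate -0.0777). That setting thus does not tell whether correlation between members undoes a shift. By fry, Sertoli cells and epithelial genes passed (adjusted p = 0.0153 each) and interferon response genes did not (0.136).

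Of 145 named genes, normexp reversed Ddx4 (1.02), Hrk (0.44), Id4 (0.23), Ocln (0.27), Piwil2 (0.85), Tekt1 (0.57) and Tex14 (0.23), whose probes were above background on no or 1 GC-2 array. The authors' log2 table reversed Nuf2 (-3.23), Psmb9 (-1.76) and Sqle (1.49), the mean of a gene's probes Vwf (-0.28), and leaving out GC-2 replicate 1 Acr (1.09), which passed at -1.50 without GC-2 replicate 2. The cause was not tested. Between 10 and 19 named genes lost their call when 1 array was left out. Signal over background limits dim genes most, and the GC-2 arrays were the dimmer.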

Other observations

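The scan of gene families, the chromosome scan and the tests of the epithelial list were chosen after the results were seen, while the tests of 3 marker lists and of further probes were set before their own values were seen but after the keratin and uroplakin genes were.

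Probes of Hoxd genes, of protocadherins of the Pcdhb cluster and of small nucleolar RNAs of the Snora class gave higher signals in GC-2 as families. RNA was amplified with an oligo-dT primer, and whether the Snora probes read the small nucleolar RNAs themselves or longer transcripts was not tested. Among 291 families that share a symbol stem and have at least 8 tested genes, 7 of 8 Hoxd genes rose with a median of 3.49 log2, 7 of 10 Pcdhb genes with a median of 2.35 log2, and 8 of 8 Snora genes with a median of 2.67 log2 (camera, adjusted p = 0.00232, 0.00419 and 0.00609). Neither these nor the other 2 families that passed did so with an estimated correlation (adjusted p = 0.996 with an estimated correlation for all 5). These medians take dim probes as measured: 2, 2 and 1 members were well above background on no GC-1 array, among them Pcdhb16 and Snora81, at least 6.04-fold and 6.81-fold higher in GC-2. With the preset correlation these 3 families stayed past the threshold under quantile normalization, cyclic loess and normexp. No direction changed under these settings or with any 1 of the arrays left out. Under normexp, however, the medians were smaller, at 2.14 log2 for Hoxd, 1.49 for Pcdhb and 1.56 for Snora. Scaled to the E1A spike-in probes, every change would be lower by about 2.06 log2 (SD 0.46 over 8 probes), which would leave the direction of the Pcdhb and Snora medians open. Of 52 Rpl and 44 Rps genes, the latter including kinases such as Rps6ka5, 12 and 11 rose and 1 and 4 fell (camera, adjusted p = 0.00232 and 0.0288), with medians of 0.53 and 0.57 log2 that would be falls if scaled to the spike-in probes, but the adjusted p was 0.532 and 0.477 under quantile normalization and 0.191 and 0.322 under normexp. Rps genes also missed the threshold without GC-1 replicate 2 or GC-2 replicate 2 (adjusted p = 0.0857 and 0.123).

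Y-linked genes were few. Of 119 probes placed on chromosome Y, 19 were well above background on both GC-1 arrays and 15 on both GC-2 arrays. Ddx3y, Uty and Eif2s3y, which most male cells express, were above background on no array, nor was Xist.

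Of 37 tested keratin and uroplakin genes, such as Krt18 and Upk1b, 19 were lower in GC-2 and 2 higher, with a mesothelial programme in GC-1 as a candidate explanation: of 22 other mesothelial markers, 1 of them also in another list, 16 fell and 2 rose, and their median of -4.35 (-3.75 with bounds) lay at the 0.01 percentile of 10000 random lists matched on signal, the smallest they can give. Msln, the mesothelin gene, fell by 7.32 log2, Efemp1 fell by 8.34 log2, Prg4 fell by 8.87 log2 and Ptgis fell by 7.20 log2, while Aldh1a2 and C2 rose. Leaving out GC-1 replicate 1 ended the calls of Aldh1a2, C2, Bnc1, Rarres2 and Ildr2, and leaving out other single arrays also ended those of C2, Bnc1 and Ildr2. With 1 array left out, the change ran from 0.99 to 1.13 log2 for C2, from -5.31 to -2.70 for Bnc1 and from -1.19 to -0.80 for Ildr2. A urothelial list of 13 lay at the 0.1 percentile with 7 lower and 3 higher, 3 of them shared with other lists, so a urothelial source stays open, while a stratified squamous list of 20 lay at the 4.89 percentile with 9 lower and 2 higher, above the limit of 2.5 set for it. Random lists were drawn gene by gene, so they lack the correlation between members of a real list. The Sertoli list, which holds Krt18 and Wt1, lay at the 0.01 percentile as well, so the test does not set mesothelium apart from it. Lists that camera did not call also lay far out, at 0.44 for junction genes and 99.93 for Leydig cells. Endothelium lay at 99.69 and extracellular matrix at 99.57, so an extreme percentile by itself separates weakly. Probes that misread a single gene stay open, since only 4 further probes were tested (100% of them lower), and neither cells of another type in the GC-1 cultures nor the identity of the line was tested.

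Genes of chromosome 3 were higher in GC-2 relative to all genes, although their own change would be a fall if scaled to the spike-in probes, by a median of 0.37 log2 over 835 genes with 219 higher and 128 lower (camera over 20 chromosomes, adjusted p = 0.0149; adjusted p = 0.364 with an estimated correlation). The adjusted p was 0.0772 without GC-2 replicate 1, and no other chromosome passed. A trend with signal level is argued against as the whole cause, since 1 of 1 chromosome still passed after it was removed (median 0.45, adjusted p = 0.0117). DNA copy differences stay open. Of its 20 Mb windows 100% (8 of 8) shared its sign. However, the windows hold the same genes for whose shift the chromosome was picked, which made a shared sign likely in advance. Chromosomes 1, 9, 11, 12, 15, 16 and 19 had all windows of 1 sign without passing, so the window test separates weakly, and no DNA was analysed here.

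The fall of the epithelial list was weighed against technical sources. Against 10000 random lists of matched signal, the list's median lay at the 0.01 percentile, the smallest they can give. With dim members at their bounds in all lists it lay at the 0.02 percentile. The fall thus exceeded that of other genes of like mean signal. However, the list was picked for its fall against other genes in these same data, which made a low percentile likely in advance. The percentiles therefore do not settle whether dimmer GC-2 arrays were the whole cause. The call ended under normexp, which compresses low signals (mean change -1.57 against -3.07, adjusted p = 0.121), so the size of the fall depends on how dim signals are treated, while with a filter on all 4 arrays it ended with 9 members left and the fall was not smaller (mean change -3.44, adjusted p = 0.0572). 1 odd array is argued against, since at least 0.914 of the mean fall was kept when any array was left out. A biological difference between the lines stays open as a hypothesis, and slide position, which follows the line, cannot be told apart from it.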
